A study of Drosophila melanogaster with 4 samples.

How the data were processed

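The deposited matrices hold counts of unique molecular identifiers (UMIs) per feature and barcode, made per the file headers by Cell Ranger 6.1.2, while the submitters' processing notes name Cell Ranger 6.0.2 and Seurat 5.1.0 with genome build BDGP6. The libraries were prepared with 10x Chromium 3′ v3.1 chemistry. The feature table held 24280 features, of which 17895 were genes, 5898 copies of transposable elements, 485 single transcripts and 2 reporters. UMIs outside gene features made up 0.474% and 0.154% of retained cells' UMIs in EE lineages 1 and 2, 0.0699% in control and 0.0924% in the library labelled Xrp1 overexpression, and were left out of clustering and CPM totals. Whether the 2 EE lineages libraries came from separate flies is not given in the sources used here, and a description of the tracing construct is not given either. The age of the flies of the unsorted libraries is also not given.

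Barcodes were retained with at least 200 genes and at most 20% mitochondrial UMIs, which left 5676 of 8885. Fewer than 200 genes were found in 184, 74, 145 and 217 barcodes, and more than 20% mitochondrial UMIs in 461, 203, 334 and 2199, of EE lineages 1, EE lineages 2, control and the library labelled Xrp1 overexpression. Doublet scores came from 2 simulated doublets per cell, and the top 0.8% per 1000 barcodes was removed, 3, 21, 13 and 102 cells, which left 5537. In a self-test with added artificial doublets the area under the curve was 0.969, 0.950, 0.944 and 0.965 in the same order. Cells were scaled to 10000 UMIs, and 2000 variable genes, 30 principal components, 15 neighbours and Leiden clustering at resolution 1 gave 32 clusters, with Xrp1 left out of clustering.

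Clusters were named from 11 marker lists, each compared as the mean log2 ratio of its genes to the median over clusters. A name needed a mean of at least 1, a margin of 0.5 over the next list and at least 3 markers raised, and these thresholds for naming were set after seeing the data. Clusters named from the EE, progenitor, EC and middle midgut lists were found, with 1.07%, 0.198%, 0.994% and 2.09% of cells in the middle midgut-like class of EE lineages 1, EE lineages 2, control and the library labelled Xrp1 overexpression, and no cluster received the name of visceral muscle, hemocyte, trachea, neuron or glia, Malpighian tubule, fat body, or germline or follicle. In EE-like cells the marker sums of these 7 lists were 72.9, 171, 16.3, 639, 192, 48.1 and 0 CPM in control and 52.6, 121, 10.5, 492, 134, 79.5 and 1.20 CPM in the library labelled Xrp1 overexpression.

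Counts of each class were summed per library where at least 20 cells were present. Between the unsorted libraries, log2 ratios were taken with a pseudocount of 5 CPM for genes of at least 10 mean CPM, with exact 95% Poisson or Clopper-Pearson intervals. Medians of 21 gene lists, of which 2 symbols were not found in the feature table, were placed among 10000 random lists matched in 20 bins of expression, for lists of at least 3 measured genes. Genes were named when they had at least 50 CPM in 1 of the 2 libraries, an absolute log2 ratio of at least 1, a value in the library labelled Xrp1 overexpression outside the range of control and both EE lineages libraries, and in the higher library at least 0.5 times the CPM of its other cells, up to 12 per direction. In the other comparison genes past the false discovery rate were named when both EE lineages libraries lay on the same side of control and the same ratio to other cells held, which kept 118 higher and 190 lower of 341 in EE-like and 8 and 18 of 60 in progenitor-like cells. A count of 0 was set to a floor of 3 counts for the least fold. EE lineages were compared with control by edgeR 4.0.16 quasi-likelihood tests with trimmed-mean scaling and a filter on low counts, and by DESeq2 1.42.0, at a false discovery rate of 0.05. The gene lists, comparisons, tests and first set of alternatives were chosen before the data were examined.

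Simulated counts had a fixed dispersion of 0.1, not estimated from the data, and 200 changed genes shared over 3 folds. There edgeR recovered 1.49%, 25.4% and 73.0% of genes changed by 2-, 4- and 8-fold in EE-like cells, 2.99%, 32.8% and 84.8% in progenitor-like cells and 2.99%, 64.2% and 95.5% in EC-like cells. False calls numbered 0, 2 and 6 in the 3 classes. Without simulated change 1 of 21 lists lay outside the random range, and with proteasome genes doubled that list had a median of 0.95 and the 100th percentile. Between the 2 EE lineages libraries the chi-square per degree of freedom was 41.3, 32.4 and 30.5 and Pearson's r across genes 0.972, 0.938 and 0.851 in EE-like, progenitor-like and EC-like cells, and 1 barcode sequence was shared.

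Alternatives covered scaling, pseudocount, expression minimum, equal weights per cell, cell filters, doublets, resolution, clustering of each library alone and leaving out clusters. A separate table of the alternatives that move or turn a reported value was made while the text was being written. Analyses ran in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, igraph 0.11.9, leidenalg 0.10.2 and matplotlib 3.10.9, and in R 4.3.3 with limma 3.58.1.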

Results

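Midgut cells of adult female fruit flies (Drosophila melanogaster) were counted by droplet-based single-cell RNA sequencing in 4 libraries. The study concerns enteroendocrine (EE) cells, the gut cells that secrete peptide hormones. The EE lineages group held 2 libraries from flies whose EE cells were lineage traced up to 7 days of age, and GFP-positive cells were sorted from them. Control held 1 library of unsorted midgut cells with the pros-Gal4 driver, which is active in EE cells, and the temperature-sensitive repressor Gal80. The remaining library, also unsorted, carried in addition a UAS transgene of Xrp1, a stress-response transcription factor of the bZIP family. Deposited matrices held 6727347 unique molecular identifiers (UMIs) in 839 barcodes of EE lineages 1, 12713071 in 1739 barcodes of EE lineages 2, 36787267 in 1461 barcodes of control and 100255835 in 4846 barcodes of the library labelled Xrp1 overexpression. After filtering, 375, 1515, 1107 and 2540 cells were retained in that order. Control and the library labelled Xrp1 overexpression have no replicate, so intervals given for them cover counting error only and no p-value was computed between these 2 libraries. Ranks among random lists and tests of explanations given below describe these libraries only.

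Xrp1 (FBgn0261113), at 18914968 to 18926989 on chromosome 3R, did not go with the overexpression label in these counts. EE-like cells held 1407 Xrp1 counts per 1000000 UMIs (CPM; exact Poisson 95% interval 1367 to 1448) in the library labelled Xrp1 overexpression and 1477 CPM (1412 to 1545) in control, a ratio of 0.952 (0.903 to 1.00). Both traced libraries lay above these values, at 3019 and 2117 CPM. In progenitor-like cells the same ratio was 1.00 (0.971 to 1.04), and in enterocyte-like (EC-like) cells it was 1.10 (1.07 to 1.13). With 3′ tags a transgene is counted only where its own 3′ end matches the annotated gene, and that sequence is not given in the sources used here, so this value may check nothing. The group is therefore called the library labelled Xrp1 overexpression, and every direction drawn from it rests on that label.

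**Figure D1:**
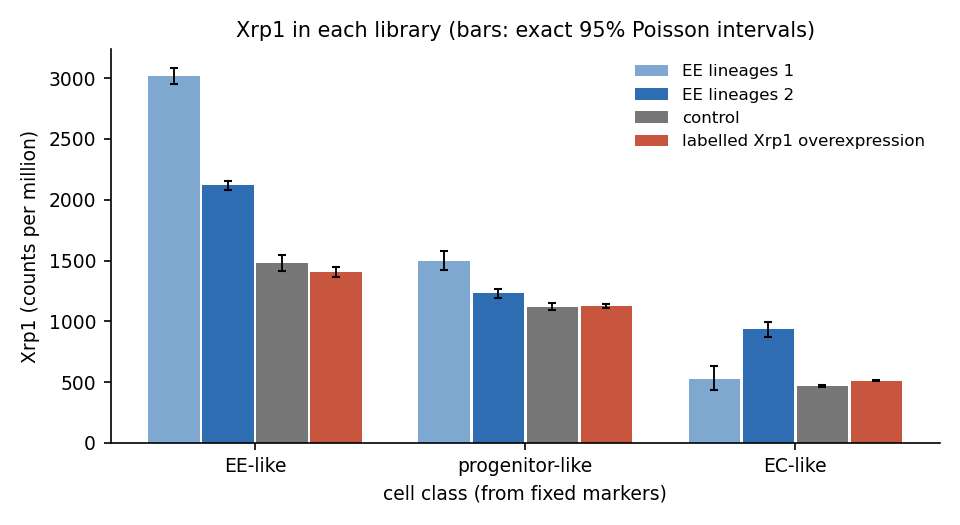
Xrp1 CPM (vertical axis) in EE-like, progenitor-like and EC-like cells of each library, with exact 95% Poisson intervals as bars. In EE-like cells control stands at 1477 and the library labelled Xrp1 overexpression at 1407, with the traced libraries at 3019 and 2117.

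Sorting for GFP went with a high share of EE-like cells. They made up 67.0% ± 11.7 (SD, n = 2) of retained cells in the EE lineages libraries, 6.05% (exact 95% interval 4.72 to 7.62) in control and 8.43% (7.37 to 9.57) in the library labelled Xrp1 overexpression. Progenitor-like cells, marked by stem cell and enteroblast genes such as esg and Dl, were 8.72% ± 1.77 (SD, n = 2) of the traced libraries, 8.67% (7.08 to 10.5) of control and 19.6% (18.0 to 21.2) of the library labelled Xrp1 overexpression. That is 143 progenitor-like cells per 100 EE-like cells in control and 232 in the library labelled Xrp1 overexpression. EC-like cells, the absorptive cells rich in trypsin and other digestive enzyme transcripts, were 4.42% ± 2.05 (SD, n = 2), 63.8% (60.9 to 66.6) and 51.0% (49.0 to 52.9) in the same order. Unnamed clusters took 26.9% and 11.6% of the traced libraries, 20.5% of control and 18.9% of the library labelled Xrp1 overexpression. Among them, cluster 13 scored nearly alike for the progenitor (2.549) and EE (2.538) lists, and its top genes included PPO2, NPF and CCHa2. It held 46 cells of control and 47 of the library labelled Xrp1 overexpression, beside 67 and 214 EE-like cells. The EE-like and progenitor-like shares of these libraries, and their ratio, therefore depend on leaving it unnamed.

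The unsorted libraries differed in quality: 45.4% of barcodes exceeded 20% mitochondrial UMIs in the library labelled Xrp1 overexpression against 22.9% in control, and retained cells had medians of 11174 and 4089 UMIs. With no mitochondrial limit, a setting chosen after seeing the data, the progenitor-like share of the library labelled Xrp1 overexpression was 11.3%, and the order of the unsorted libraries turned for the EE-like share, at 5.84%, below control, and for the EC-like share, at 62.0% against 60.03%. The mean EC-like share of the traced libraries lay between 0% and 18.2% over the settings. EC-like cluster 7 held 265 of the 706 EC-like cells of control and 1 of 1295 in the library labelled Xrp1 overexpression.

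**Figure D2:**
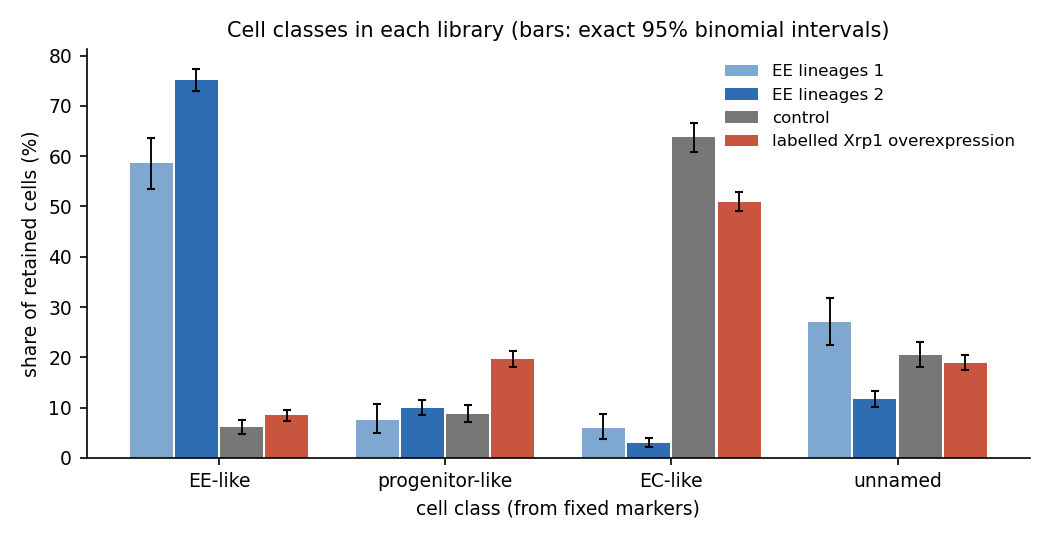
Share of retained cells (%, vertical axis) in each named class and in unnamed clusters, by library, with exact 95% binomial intervals as bars. EE-like cells are 58.7% and 75.2% of the sorted libraries and 6.05% and 8.43% of the unsorted libraries, whereas progenitor-like cells are 8.67% of control and 19.6% of the library labelled Xrp1 overexpression.

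Which genes differ in EE cells that carry the Xrp1 transgene was asked by comparing EE-like cells of the 2 unsorted libraries. The metallothionein genes MtnE, MtnD and MtnA, whose products bind copper and zinc, were higher in the library labelled Xrp1 overexpression: MtnE at 4832 CPM against 202 in control, 23.9-fold (21.2 to 27.2), MtnD at 4402 against 343, 12.8-fold (11.7 to 14.1), and MtnA at 2441 against 308, 7.93-fold (7.16 to 8.79). The traced libraries lay between these values, with MtnE at 2029.7 and 683 CPM, and middle midgut marker RNA in EE-like cells was at 7909 and 4466 CPM there, 1837 in control and 6217 in the library labelled Xrp1 overexpression. That marker list itself holds MtnB and MtnC, so this sum is not independent of metallothionein RNA. In EE-like cluster 4, which expresses the hormone gene CCHa2, MtnE stood at 17718 CPM against 679 in control, whereas in cluster 21 it was at 92.9 against 93.3. Among genes of heat shock proteins, 10 of 12 measured were higher, with a list median of 0.38 on the log2 scale, 0.45 above the median of all measured genes. Control was the low library for several of them, as the traced libraries, without the transgene, stood at 475 and 238 CPM for Hsp68 beside 288, and at 139 and 88.1 for Hsp70Bc beside 85.5. Lower in this library were the hormone genes CCHa1 and CCHa2, with a CCHa1 log2 ratio of -0.93 when EE-like clusters were weighted equally, and 10 of 12 measured genes of lipid metabolism. Summed RNA of 14 peptide hormone genes was 81309 CPM against 101333 in control.

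Other genes higher by the fixed rule included CG9289, at 236 CPM against 0 UMIs in control, at least 101-fold higher against a floor of 3 counts in that library. CG30466 stood at 163 against 4.66 CPM, lncRNA:CR42646 at 59.2 CPM against 0 UMIs, at least 25.4-fold higher, and Cyp4p2, a cytochrome P450 gene, at 83.4 against 3.10 CPM. CG40470 was at 73.8 CPM beside 1 UMI in control, a ratio of 95.1 (16.9 to 3772). CG4210, CG9360, l(2)41Ab and CG6277 lay between 7.16-fold and 9.401-fold higher, and with each library clustered alone the log2 ratios of CG9360 and CG30466 were 0.02 and 0.97. At the low end, CG34386 stood at 0.299 CPM against 282 and Mip at 1.49 against 139.7, but the control UMIs of these genes came from 3 and 4 cells. Without the 5 EE-like clusters that are near absent from the unsorted libraries, a setting chosen after seeing the data, their log2 ratios were -0.13 and -0.03, and that of AstC, lower at 1244 against 3613 CPM with all clusters, was -0.07. CG9568 was lower at 355 against 1784 CPM (ratio 0.199, 0.185 to 0.214), as were CG6357, CG4629, CG14292, CG3868, CG14312, CG40472 and M7BP, with ratios from 0.187 to 0.381, of which CG14312, M7BP and CG14292 fell short of the naming threshold under other settings, at -0.95, -0.98 and -0.92 on the log2 scale.

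Over the 21 lists fixed before the data were examined, the EE-like medians of 6 lists lay above and 1 below the central 95% of 10000 random lists matched in size and expression. All measured genes had a median of -0.08, which scaling by trimmed means of M-values (TMM) moved by 0.11. For the 4 measured cell cycle genes, of 26 in the list, all higher, the median was 0.76 (99.87th percentile). The ribonucleotide reductase genes led, RnrS at 23.0 against 3.10 CPM and RnrL at 22.1 against 7.76. Both lay under the expression minimum in control and passed it only through their values in the library labelled Xrp1 overexpression. The minimum can thus select changed members, and without it the median was 0.084. The rank therefore describes these 4 genes and cannot show a shift of the list. Heat shock genes stood at the 99.98th percentile, led by Hsp70Bc at 85.5 against 26.4 CPM, Hsp68 at 288 against 101 and Hsp26 at 1555 against 617. Cytosolic ribosomal protein genes had a median of 0.18 (99.87th), with 71 of 81 higher, but -0.17 with each library clustered alone and 0.077 at resolution 0.5, and RpL22 was the exception in size at 351 against 823 CPM. The digestive enzyme median was 0.55, above all 10000 random lists: yip7 was higher at 235 against 61.3 CPM and epsilonTry at 214 against 58.2, while Mal-A1 was lower at 55.6 against 474 and Amy-d at 22.7 against 139.7. Insulin and growth genes had a median of 0.26 (98.95th), with ImpL2 at 86.7 against 39.6 CPM, but -0.019 with each library clustered alone, and nuclear-encoded respiratory chain genes one of 0.00 (97.96th), with 33 higher and 31 lower. Lipid metabolism lay below at -0.35 (0.79th), with FASN1, a fatty acid synthase gene, at 206 against 342 CPM and SREBP at 96.5 against 145, and its direction was lost with each cell weighted equally (0.0058).

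Within the random range in EE-like cells lay the Xrp1-associated genes, with a median of -0.18 (6.48th percentile), 6 higher and 15 lower. GstE7 had the largest absolute log2 ratio with the pseudocount of 5 CPM, at 382 against 687 CPM. The other lists within it were peptide hormones (-0.07), peptide processing and secretion (-0.06), EE transcription factors (0.19), JAK-STAT (0.05), EGFR (-0.01), JNK (-0.17) and apoptosis (-0.35, 3.38th). So did ER stress and integrated stress response (-0.22), glutathione transferases and antioxidants (-0.03), autophagy and lysosome (-0.08), proteasome (0.00), antimicrobial and immune (-0.22) and Notch (-0.06). EC marker RNA in these cells summed to 3171 CPM in the library labelled Xrp1 overexpression and 2600.2 in control, and the median mitochondrial share was 5.85% and 4.01%. Most EE-like cells of both libraries came from clusters 4, 25, 11, 21 and 22, and without cluster 21, whose cells held 4.09 times the median UMIs of their library, the medians were 0.10 for heat shock, 0.26 for ribosomal protein and -0.19 for digestive enzyme genes. The cell cycle median was 0.08 with no expression minimum, the digestive median was then -0.05, and the respiratory median was below 0 under 6 other settings.

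**Figure D3:**
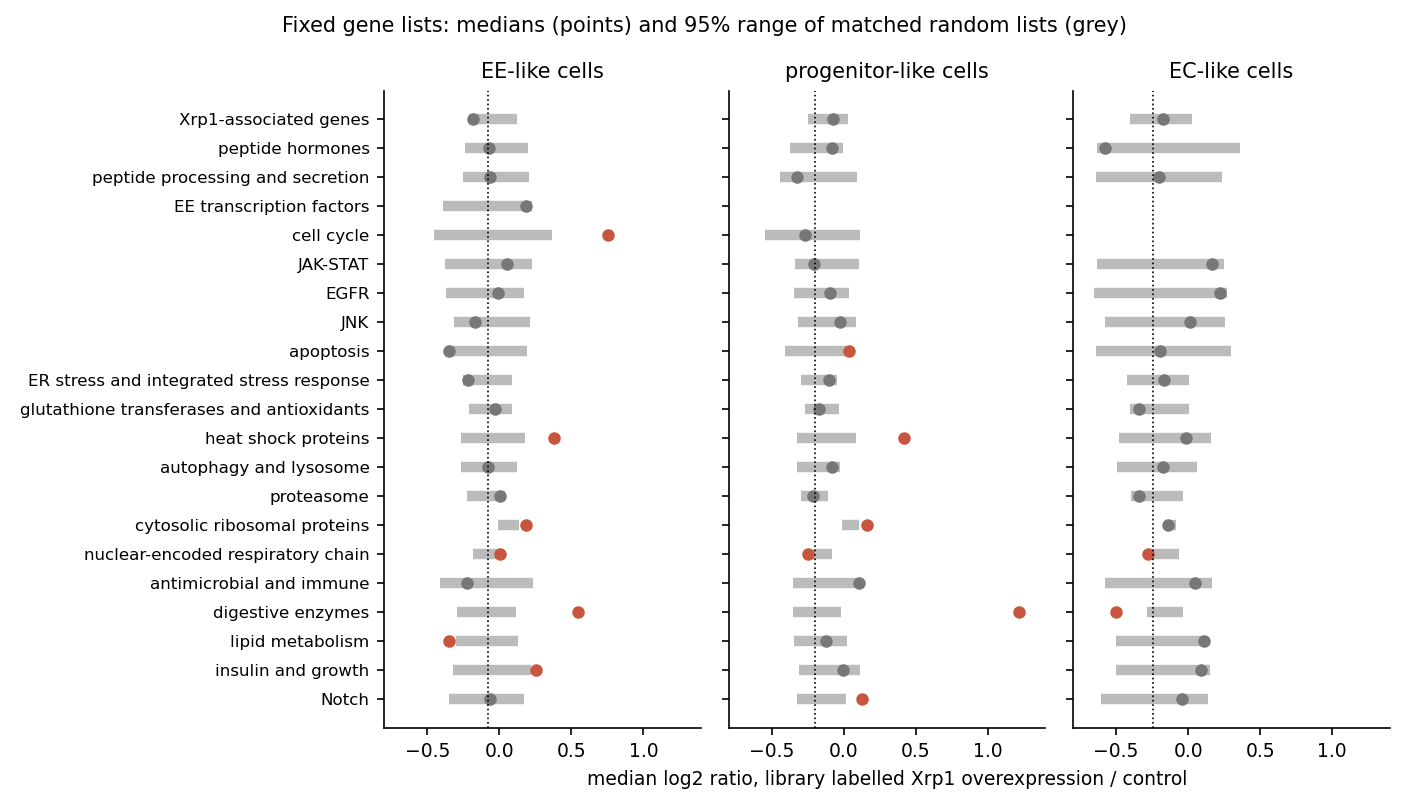
Median log2 ratio of the library labelled Xrp1 overexpression to control (horizontal axis) for each fixed gene list in 3 cell classes, with the central 95% of matched random lists in grey and medians outside it in red; the dotted line is the median of all genes (-0.08, -0.20 and -0.24). Digestive enzyme genes have medians of 0.55, 1.22 and -0.50 in EE-like, progenitor-like and EC-like cells.

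Several peptide hormone genes differed in EE-like cells between sorted and unsorted libraries. AstA was counted at 3077 ± 175 CPM (SD, n = 2) in EE lineages and at 0 UMIs in both unsorted libraries, where 0 of 67 and 0 of 214 cells had a UMI, which at 3 counts allows up to 4.48% and 1.402% of cells with a UMI and does not limit the share of cells expressing the gene. AstC stood at 29988 ± 6808 CPM (SD, n = 2) in EE lineages, 3613 in control and 1244 in the library labelled Xrp1 overexpression. NPF went the other way, at 1008 ± 245 CPM (SD, n = 2), 18968 and 22005. CCHa2 was at 42683 ± 9617 CPM (SD, n = 2), 42085 and 23371, Orcokinin at 17287 ± 1032 (SD, n = 2), 31638 and 30131, and Tk at 2603 ± 1652 (SD, n = 2), 3677 and 3284. Between the unsorted libraries the ratio to control was 0.344 (0.330 to 0.359) for AstC, 0.202 (0.179 to 0.227) for CCHa1, 0.555 (0.549 to 0.561) for CCHa2, 1.16 (1.14 to 1.18) for NPF and 4.15 (3.67 to 4.72) for Nplp2. After thinning each cell to 1000 UMIs, 19.0% of EE-like cells of control and 15.5% of the library labelled Xrp1 overexpression had an AstC UMI, beside 0.350% and 0.416% of EC-like cells. For NPF these were 30.2% and 42.7%, beside 1.05% and 2.16% of EC-like cells, for CCHa2 42.9% and 32.4%, beside 1.92% and 5.07%, and for Orcokinin 58.7% and 45.1%, beside 1.399% and 4.33%. Before thinning, 28.4% and 21.5% of EE-like cells had an AstC UMI at median depths of 11137 and 10604 UMIs. Hormone genes are among the markers that define the class, and the AstC-expressing clusters 5, 14, 15, 17 and 26, near absent from the unsorted libraries, held 3 of the 67 EE-like cells of control and 0 of the library labelled Xrp1 overexpression, so the AstC and Mip differences between the unsorted libraries rest on these cells. Cluster 22, held by all libraries, also expresses AstC, at 11724 CPM in control and 9017 in the library labelled Xrp1 overexpression. Without deep cluster 21 the summed hormone RNA was 156061 CPM in control and 120556 in the library labelled Xrp1 overexpression.

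**Figure D4:**
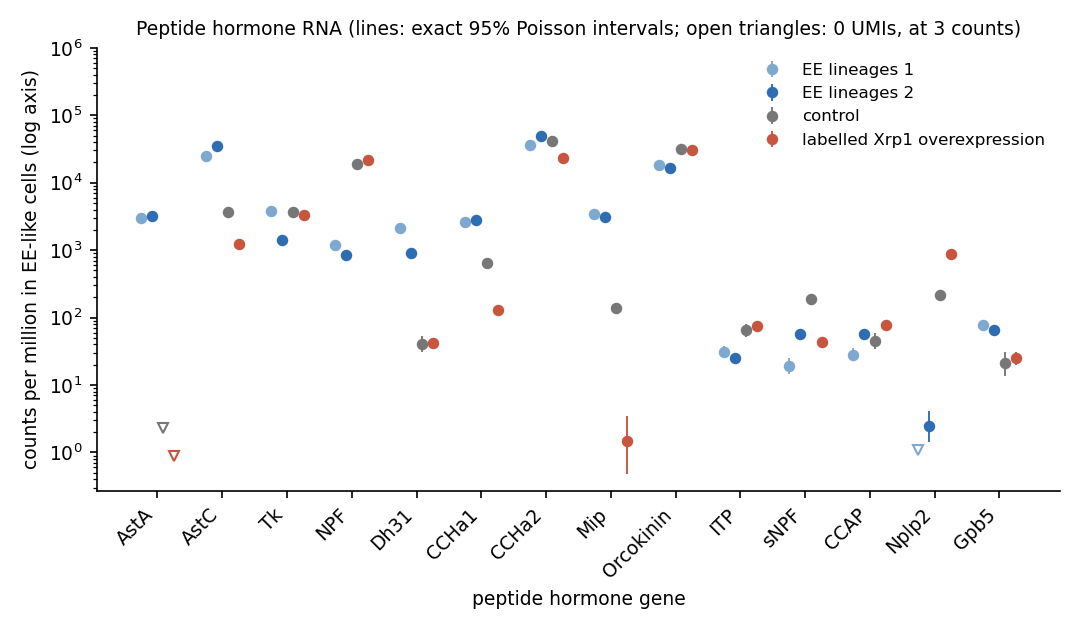
CPM of 14 peptide hormone genes in EE-like cells of each library (logarithmic vertical axis), with exact 95% Poisson intervals as lines and open triangles at 3 counts where none was found. AstC is at 25174 and 34802 in the traced libraries and at 3613 in control, whereas NPF is at 1182 and 835 there and at 18968 in control.

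In progenitor-like cells, where the pros driver is not usually active, the heat shock genes Hsp26 and Hsp23 and 8 of 10 measured digestive enzyme genes were higher in the library labelled Xrp1 overexpression. Hsp26 stood at 205 against 40.1 CPM and Hsp23 at 153 against 36.3, with 6 of 9 heat shock genes higher and a list median of 0.42, 0.61 above that of all genes, which was 0.25 as the mean of CPM per cell and 0.68 under TMM scaling. Digestive enzyme genes had a median of 1.22, led by epsilonTry at 82.5 against 15.9 CPM and Jon65Aiv at 176 against 50.7, and Jon25Biii was lower at 2.41 against 25.2. The digestive median was 0.04 with no minimum mean CPM, 0.52 with at least 500 genes and 0.34 with no mitochondrial limit. EC marker RNA in the class summed to 1221 CPM in the library labelled Xrp1 overexpression against 625 in control. In EC-like cells epsilonTry and Jon25Biii had the same directions at far higher levels, 14981 against 5427 and 374 against 5609 CPM. Other members were not compared. The ratio to other cells was not required of lists, so RNA from EC-like cells remains a possible source of the digestive difference. Median mitochondrial shares of progenitor-like cells were 4.75% and 3.85%. Singly named genes were CG9289 (0 UMIs in control and 239 CPM, at least 331-fold higher), CG30466 (3.61 and 267 CPM) and its neighbour Flo1, a flotillin gene (92.6 and 370.3 CPM). Also higher were drpr, an engulfment receptor gene, at 139 against 48.3 CPM, Chs2, a chitin synthase gene, at 51.3 against 22.1, and kirre, Cipc, CG11885, galectin and CG9360. Lower were Act42A, an actin gene, at 317 against 785 CPM, bnl, an FGF ligand gene, at 106 against 240.2, and Shrm, lncRNA:CR32368, Dmtn and CG8620. Under TMM scaling bnl, lncRNA:CR32368, Dmtn and CG8620 fell short of the naming threshold, with log2 ratios of -0.86, -0.89, -0.87 and -0.75. So did kirre as the mean of CPM per cell (0.81), Chs2 with a pseudocount of 20 CPM (0.76) and CG9360 with at most 10% mitochondrial UMIs (0.986).

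In this class 5 of 20 lists lay above and 1 below the random range. TMM scaling moved all values by 0.29, so medians are best read against that of all genes, -0.20. Cytosolic ribosomal protein genes had a median of 0.16 (above all 10000 random lists), 0.36 above all genes, with 73 of 81 higher. Notch pathway genes had a median of 0.13 (99.89th percentile), 0.33 above all genes, with 7 of 10 higher, led by E(spl)m3-HLH at 290.2 against 239 CPM, and -0.19 when each cell was weighted equally. The apoptosis median was 0.04 (98.58th), 0.24 above all genes, and also changed sign with equal weights per cell, at -0.07. Respiratory chain genes had a median of -0.25 (0.10th), 0.05 below all genes. Under TMM scaling their median became 0.03, beside 0.09 for all genes. The remaining 14 lists lay within the random range, among them the Xrp1-associated genes, 0.12 above all genes, and proteasome genes, 0.02 below.

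In EC-like cells digestive enzyme genes differed in both directions, with 15 higher and 19 lower. Jon25Bii was higher in the library labelled Xrp1 overexpression at 772 against 64.1 CPM (12.04-fold, 11.4 to 12.7), Jon25Bi at 1505 against 191 and CG12374, a gene of the carboxypeptidase family, at 30131 against 8097, whereas Jon25Biii was lower at 374 against 5609 and CG10472 at 205 against 1807. Their median was -0.50, below all 10000 random lists and 0.26 below all genes. Also higher were CG32302 (77.8 against 3.39 CPM), the myosin light chain gene Mlc2 (276 against 50.01), CG17192, CG4830, CG33346, Gbp2, CG4563, mwh and Ser6, the last with a log2 ratio of 0.44 as the mean of CPM per cell. Lower were the neighbouring genes CG7916, CG7953, CG8997 and CG33306, with ratios from 0.00513 to 0.0245, and CG17571, CG12057, mag, Ser8, Alp5 and lambdaTry. At a clustering resolution of 0.5 the log2 ratio of CG33306 was 0.10, that of CG12057, whose 3427 control UMIs came from 6 cells, -0.02, that of lambdaTry -0.02, that of Ser8 -0.11 and the digestive list median -0.08. Respiratory chain genes lay below the random range at -0.28 (1.29th percentile), 0.04 below all genes, with 63 of 64 lower. TMM scaling, which moved all values by 0.36, put their median at 0.07 and that of all genes at 0.12, so it changes the sign but not the order. The other 17 of 19 lists lay within the range, with the Xrp1-associated genes 0.07 above all genes. Cluster 7 and cluster 9 are held unequally, at 37.5% and 1.98% of EC-like cells in control and 0.0772% and 16.4% in the library labelled Xrp1 overexpression, whose median mitochondrial share was 6.64% against 2.07% and EC marker RNA 141621 against 103378 CPM. Cluster 27, with Jon25Biii, CG17571 and CG7916 among its top genes, held 4.39% of EC-like cells in control and 0.695% in the library labelled Xrp1 overexpression. A different mix of EC-like clusters may thus account for falls of these genes. Leaving out cluster 7 alone, a setting chosen after seeing the data, kept Jon25Biii, CG17571 and CG7916 past the naming threshold. The share of the other clusters in these falls was not tested.

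What distinguishes traced and sorted EE cells from EE cells of whole midguts was asked with edgeR's quasi-likelihood test on counts summed per library. In EE-like cells, AstA, a gene of a gut peptide hormone, was at 3077 ± 175 CPM (SD, n = 2) in EE lineages and 0 UMIs in control, at least 1322-fold higher (adjusted p = 1.9e-04). Mip rose by 4.58 on the log2 scale (SE 0.69, adjusted p = 0.0033), Dh31 by 5.23 (SE 0.77, adjusted p = 0.0030) and AstC by 3.10 (SE 0.73, adjusted p = 0.030), and Gpb5 was also higher. NPF fell by 4.21 (SE 0.57, adjusted p = 0.0019), and so did sNPF (log2 fold change -2.21, SE 0.53, adjusted p = 0.033) and Nplp2 (-6.95, SE 0.66, adjusted p = 2.2e-04). EE-like cells of the 2 groups lie in different clusters: AstA and Mip RNA came mainly from clusters 5 and 17, which held 2 of 67 control cells, and AstC RNA from clusters 5, 14, 15 and 17, while in cluster 4, held by all libraries, Mip was at 8.18 and 53.1 CPM against 3.90 in control. NPF and Nplp2 came mainly from cluster 25, with 13 of 67 EE-like cells of control against 2 of 220 and 3 of 1140 in the traced libraries, whereas Dh31 stood at 8860 and 4214 CPM against 393 within shared cluster 11. Of the 14 hormone genes, 5 rose and 3 fell, or 6 and 4 adjusted over the list alone. The EE identity factor gene pros rose by 3.20 (SE 0.66) and drm by 3.33 (SE 0.87), while tap, a proneural factor gene, fell by 2.77 (SE 0.46); these were 2 and 1 of 7 EE transcription factor genes, or 2 and 2 adjusted over the list alone.

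Among signalling lists the calls in EE-like cells were downward in EE lineages. In the EGFR list 4 of 10 genes fell, namely the ligand gene vn by 3.61 (SE 0.39), the protease gene rho by 3.08 (SE 0.38), aos by 3.34 (SE 0.77) and sty by 1.72 (SE 0.40), and adjusted over the list alone there were also 4. In the Notch list 4 of 9 fell, namely E(spl)malpha-BFM, N, E(spl)m3-HLH and klu, or 5 adjusted over the list alone. The cytokine genes upd2 and upd3 fell by 1.85 (SE 0.41) and 1.88 (SE 0.39), 2 of 8 in the JAK-STAT list and 2 adjusted over the list alone. Upd3 and the JNK target gene Ets21C, which fell by 2.75 (SE 0.40), were 2 of 21 Xrp1-associated genes, where 3 rose and 2 fell adjusted over the list alone, and Ets21C was 1 of 9 in the JNK list (1 higher and 1 lower adjusted over the list alone). Progenitor marker RNA in these cells summed to 404 and 491 CPM in the traced libraries against 1521 in control, and the 4 Notch genes that fell are among those markers. Deep cluster 21 had the progenitor list as its second best, with a mean log2 ratio of 2.91. It held 9 of 67 EE-like cells of control against 2 of 220 and 43 of 1140 in the traced libraries. Without that cluster, a setting chosen after seeing the data, 207 genes were higher and 202 lower over all genes tested in EE-like cells. These totals do not tell which members of these lists still fell, and how far the falls in these lists rest on that cluster was not tested.

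Of 31 digestive enzyme genes 7 rose, 2 fell and 22 did not pass the threshold, or 11 rose and 3 fell adjusted over the list alone. Mal-A3, a maltase gene, was at 322 ± 34.2 CPM (SD, n = 2) against 3.10 in control, Jon65Aiv rose by 5.09 (SE 0.78), and Amy-d fell by 4.36 (SE 0.39) and Amy-p by 2.24 (SE 0.41). EC marker RNA in these cells was 7114 and 10105 CPM in the traced libraries against 2600.2 in control. Jon65Aiv and the lipid gene Npc2d are top genes of EE-like cluster 14, which held 9 and 113 cells of the traced libraries and 0 of control. Cluster 15, with the digestive gene Jon99Fi among its top genes, held 23 and 92 cells of the traced libraries and 0 of control. Lipid genes Npc2d, Npc2e and FASN2 rose, 3 of 17, or 5 higher and 1 lower adjusted over the list alone. Heat shock genes Hsp67Ba, Hsp70Bb and Hsp70Bc rose by 2.93 (SE 0.59), 4.30 (SE 0.91) and 2.12 (SE 0.49), 3 of 16, or 7 adjusted over the list alone, and the Hsp70 copies share near-identical sequence. PGRP-SD and PGRP-LC fell, 2 of 7 immune genes (2 higher and 2 lower adjusted over the list alone), and Nmdmc, GstD3 and RpL22 fell as the only members past the threshold in the ER stress, glutathione transferase and ribosomal lists. In those lists 0, 1 and 0 members rose and 1 fell in each adjusted over the list alone. No member of the lists of peptide processing, cell cycle, apoptosis, autophagy, proteasome, respiratory chain, and insulin and growth genes passed edgeR's test over all genes or adjusted over the list alone. Xrp1 was not past the threshold (log2 fold change 0.82, SE 0.56, adjusted p = 0.50).

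In all, 141 genes were higher and 200 lower in EE lineages among 7493 tested in EE-like cells. By the fixed rule the largest rises in fitted log2 fold change included sisA, at 558 ± 102 CPM (SD, n = 2) beside 1 control UMI. CG7778 (at least 11.6-fold higher), Try29F, sand and Jon99Fi were also among them. So were CG42826, bnk, lncRNA:CR43643, lncRNA:CR46350 and lncRNA:CR46481, with 0 UMIs in control and means of only 7.70 to 11.3 CPM in EE lineages. Their high rank goes with the count of 0, as they were at least 3.31-fold to 4.86-fold higher. The largest falls included ppk18, a gene of the degenerin and sodium channel family, at 1.21 ± 0.826 CPM (SD, n = 2) against 122, CG45061 at 38.8 ± 33.1 (SD, n = 2) against 2323, CG11825, CadN, dpr11, TotA, Chs2, CG14626, asRNA:CR45600 and lncRNA:CR40469. Sorting, genotype, tracing and library go together in this comparison, and an age is given only for the traced flies. The single control library was assumed to vary like the 2 traced libraries, whose labels do not say whether they came from separate flies. In every class the p-values therefore rest on the 2 traced libraries, with 1 residual degree of freedom per gene, and on a spread that edgeR pools over genes. They cannot measure the spread between control samples, and a gene can pass although its 2 traced libraries differ widely. Without the 5 EE-like clusters near absent from control, a setting chosen after seeing the data, 64 genes were higher and 67 lower, and over all settings from 40 to 384 genes were higher and from 67 to 444 lower.

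In progenitor-like cells fewer genes passed the test, 35 higher and 25 lower among 6835. AstA-R1, a receptor gene of the AstA hormone, was at 5.08 and 78.1 CPM in the traced libraries against 1.92 in control (log2 fold change 4.68, SE 0.76, adjusted p = 6.7e-07), and sens-2 rose by 2.90 (SE 0.66). Also higher by the rule were RunxB (at least 8.29-fold), tei, Prip, HP1D3csd, tow and Nazo. CG9021 fell by 4.39 (SE 0.61, adjusted p = 2.3e-09) and Cyp6a23 by 3.49 (SE 0.60), with disco-r, Obp44a, CG34386, Dgp-1, CG6912, CG34353, snRNA:U5:63BC, asRNA:CR45600, lncRNA:CR43855 and lncRNA:CR44138. The direction for CG34386 turned, to 3.97, with no mitochondrial limit. Hormone genes past the threshold, Dh31, Mip and Orcokinin upward and NPF and CCHa1 downward, were 3 and 2 of 11 (5 and 2 adjusted over the list alone) and rested on few cells. The 545 Dh31 UMIs of EE lineages 2 came from 6 of its 151 cells, and Orcokinin stood at 444 CPM in EE lineages 2 but at 4.06 in EE lineages 1, below control at 13.7. Mal-A6 and mag rose, 2 of 23 digestive genes (5 higher and 2 lower adjusted over the list alone), and mag and Npc2e were 2 of 15 lipid genes, with 3 adjusted over the list alone. No member of the other 18 lists passed edgeR's test over all genes, and 1 member passed adjusted over the list alone in each of 4 lists, namely cell cycle and immune genes upward and Xrp1-associated and glutathione transferase genes downward. DESeq2 called 7 higher and 4 lower, and edgeR called 0 of the 10430 genes with no filter on low counts and 0 at a clustering resolution of 2, where 265 and 152 genes had unadjusted p-values under 0.05.

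In EC-like cells, which number 22 and 45 in the traced libraries, edgeR called 0 of 4574 genes in either direction. There were 412 genes with an unadjusted p under 0.05, and DESeq2 called 22 higher and 5 lower. The count of 0 depends on the settings, as edgeR called 72 higher and 41 lower with no filter on low counts, 48 and 9 with doublets kept, 41 and 5 at resolution 0.5 and 119 and 29 with no mitochondrial limit. Of the 38 digestive enzyme genes 1 was higher and 5 lower adjusted over the list alone, of 9 hormone genes 5 were higher and 1 lower, and of 15 lipid genes 1 was higher. Hormone RNA in this class can rest on few cells. The 109 AstA UMIs of EE lineages 2 came from 1 of its 45 EC-like cells and the 85 Mip UMIs from 4. Carry-over from EE-like cells was not tested. In counts simulated with a fixed dispersion of 0.1 the test found 95.5% of 8-fold, 64.2% of 4-fold and 2.99% of 2-fold changes in this class. The same shares were 73.0%, 25.4% and 1.49% in EE-like and 84.8%, 32.8% and 2.99% in progenitor-like cells. That dispersion was not estimated from these libraries, so the shares may not hold here. The 9 EC-like hormone genes had a median log2 fold change of 2.98, and 0 passed the threshold over all genes.

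The matrices also counted EGFP and DsRed transcripts, examined after the feature lists were seen. EGFP in EE-like cells stood at 400.3 and 244 CPM in the traced libraries, 2.33 in control and 8.67 in the library labelled Xrp1 overexpression, and DsRed at 789 and 569 CPM in the traced libraries and 0 UMIs in the others. In progenitor-like cells EGFP was at 92.4 and 102 CPM in the traced libraries, against 0.481 and 1.54 in the unsorted ones, and DsRed at 2.03 and 10.9 CPM. EGFP UMIs were seen in 85.0% and 66.3% of EE-like cells, 28.6% and 56.3% of progenitor-like cells, and 0% (0 of 22, which at 3 counts allows up to 13.6% of cells with a UMI) and 17.8% of EC-like cells of the traced libraries. Median depths were 11071 and 4792 UMIs in EE-like, 32429 and 18209 in progenitor-like and 1614 and 12731 in EC-like cells. After thinning to 1000 UMIs, 29.2% and 24.0% of EE-like, 3.85% and 10.0% of progenitor-like and 0% and 2.63% of EC-like cells had an EGFP UMI.

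**Figure D5:**
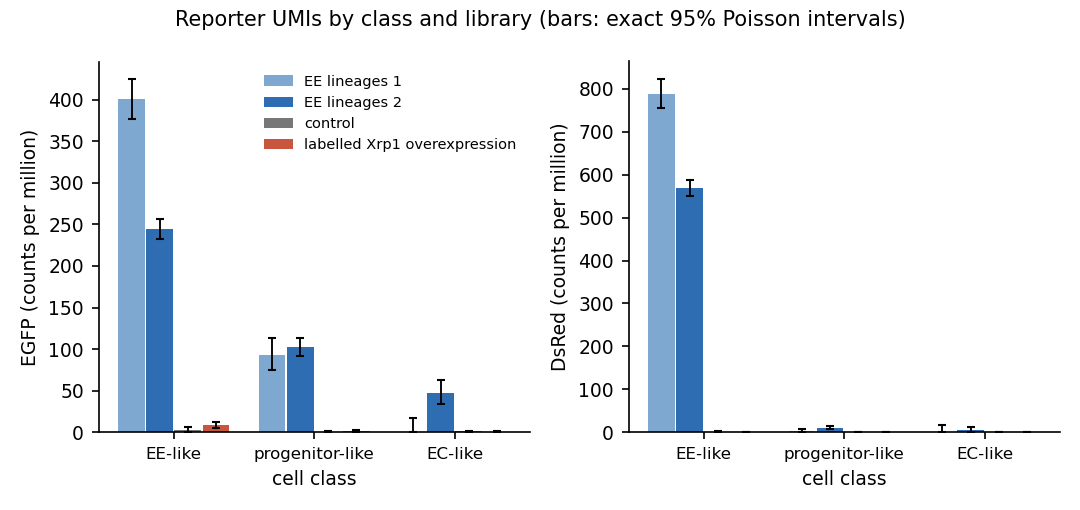
EGFP and DsRed CPM (vertical axes) by cell class and library, with exact 95% Poisson intervals as bars. In progenitor-like cells of the traced libraries EGFP is at 92.4 and 102, whereas DsRed is at 2.03 and 10.9.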

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

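Medians of 2 gene lists differed between cell classes in the comparison of the library labelled Xrp1 overexpression with control. For nuclear-encoded respiratory chain genes the log2 median in EE-like cells was above that in progenitor-like cells by 0.25 and above that in EC-like cells by 0.29. For digestive enzyme genes it was above EC-like cells by 1.05 in EE-like cells and by 1.72 in progenitor-like cells. Different members pass the expression minimum in each class, and with no minimum mean CPM the digestive medians were -0.045, 0.035 and -0.17 in EE-like, progenitor-like and EC-like cells, and the EE-like median was -0.19 without the deep EE-like cluster. Much of the respiratory difference goes with scaling, as the medians of all genes were -0.08, -0.20 and -0.24 in the same order, and under TMM scaling the respiratory medians were 0.11, 0.029 and 0.073. The difference between classes was not tested, as each library is single. Carry-over of digestive enzyme RNA from EC-like cells into the other classes was not tested either.

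Features other than genes were examined because the matrices hold them. The transposable element copia stood at 2072 CPM in EE-like cells of the library labelled Xrp1 overexpression against 90.0 in control, invader1 at 60.2 CPM in EE-like cells of EE lineages 1 beside 3 UMIs in control, and R2 at 113 CPM in EC-like cells of EE lineages 2 and 103 in those of the library labelled Xrp1 overexpression against 7.94 in control. EGFP stood at 400.3 and 244 CPM in EE-like and 92.4 and 102 CPM in progenitor-like cells of the traced libraries, and DsRed at 789 and 569 CPM in their EE-like cells.

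EGFP with few DsRed UMIs in progenitor-like cells of the traced libraries was examined with tests all chosen after the result was seen. DsRed made up at most 9.68% of both reporters' UMIs there, against 66.3% and 70.0% in EE-like cells, so free RNA from EE-like cells is excluded as the main source. Progenitor-like cells with at least 5 EGFP UMIs held at most 0.649 hormone UMIs per EGFP UMI. EE-like cells with at least 5 EGFP UMIs held 222 and 210, and all EE-like cells 238 and 464, which excludes doublets with EE-like cells as the main source. Descent from pros-expressing cells and activity of the driver in progenitor-like cells both remain possible, as pros stood at up to 6.75 CPM in those cells, and at 7.90 and 24.1 CPM in progenitor-like cells with any EGFP UMI, and either could leave such levels.

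For copia in EE-like cells the test on mitochondrial share was chosen before and the others after the result was seen. Its ratio to control was 1.07 in progenitor-like cells, so a difference carried alike by all cell types is excluded, and the lowest ratio over 5 EE-like clusters was 4.31, so a single group of cells is excluded. Among cells at or below the control median mitochondrial share the ratio was 21.0, which excludes cells with many mitochondrial UMIs as the only source. Copia was nonetheless higher above that share in each library, at 2299 against 1286 CPM in the library labelled Xrp1 overexpression. This library exceeded the 20% mitochondrial limit in 45.4% of barcodes against 22.9% in control. EE lineages 1, the traced library with more copia, did so in 54.9% against 11.7% in EE lineages 2. Damage of a whole library is therefore not excluded. The 2 libraries of 1 genotype, EE lineages 1 and 2, differed 8.61-fold, so variation between libraries might account for part of it and the effect of the transgene is open.

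For CG9289 the tests were all chosen after the result was seen. Its CPM in progenitor-like cells was 1.01 times that in EE-like cells, which excludes RNA from EE-like cells, and the EC-like level was 0.0797 of the progenitor-like level, which excludes free RNA from another source. The 5 neighbouring genes had a median log2 ratio of -0.11 in progenitor-like cells, beside -0.20 for all genes there. This argues against a gain that reaches these neighbours, but they cannot show one confined to the gene itself. With UMIs in 76.9% of progenitor-like cells, where pros is not usually active, a strain variant at the gene is a candidate explanation and an effect of the transgene is not excluded.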

How the results depend on the processing

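Control and the library labelled Xrp1 overexpression have 1 library each, so their values carry no replicate error, and genotype, sorting and depth go together with library. Settings called added were chosen after seeing the data: the 10% mitochondrial limit and clustering of each library alone for gene lists and gene counts, no mitochondrial limit, and leaving out or weighting clusters. No paired analysis was possible because control has only 1 library. The cause of the shifts was not tested. EC-like tests were not run with at least 500 genes, at most 10% mitochondrial UMIs or each library clustered alone, nor progenitor-like tests at the last 2, because a library then had fewer than 20 cells. Leaving out 1 EE lineages library gave 58.7% to 75.2% EE-like, 7.47% to 9.97% progenitor-like and 2.97% to 5.87% EC-like cells and 95294.5 to 113343 CPM of summed hormones.

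Of 78 alternatives for class shares 23 moved and 55 stayed. Of 218 for the 15 list medians outside the random range, 25 moved, 19 reversed and 174 stayed, and of 644 for the other lists 71 moved and 573 stayed. These counts include TMM and DESeq2 scaling, which shift all genes of a class nearly alike and leave a list's distance from all genes nearly unchanged. Gene counts moved in 35 of 56, summed hormones in 11 of 20, single hormones in 123 of 280, hormone shares in 43 of 56, the EE-like Xrp1 ratio in 6 of 16 and the other Xrp1 ratios in 9 of 27. Among 509 alternatives for named genes of EE lineages 58 moved, 71 weakened, 1 reversed and 379 stayed, and among 928 for named genes of the unsorted libraries 542 moved, 1 reversed and 385 stayed.

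Class shares with at least 500 genes were EE-like 7.99% in control and 10.5% in the library labelled Xrp1 overexpression, progenitor-like 12.9% and 24.3%, and EC-like 59.3% and 45.8%. With at most 10% mitochondrial UMIs they were EE-like 8.47% and 14.4%, progenitor-like 21.5% in the library labelled Xrp1 overexpression and 6.11% in EE lineages, and EC-like 44.2% in the library labelled Xrp1 overexpression. With each library clustered alone, EE-like cells were 6.38% of the library labelled Xrp1 overexpression, and progenitor-like cells 12.9% and EC-like cells 0% of EE lineages. With no mitochondrial limit (added) the library labelled Xrp1 overexpression had 5.84% EE-like, 11.3% progenitor-like and 62.0% EC-like cells, control 60.03% EC-like and EE lineages 15.1% EC-like. EC-like cells were 17.3% of EE lineages with doublets kept and 18.2% at resolution 0.5, 52.4% of control without the EC-like cluster held by control (added), and EE-like cells 49.3% of EE lineages without the EE-like clusters near absent from the unsorted libraries (added).

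The EE-like Xrp1 log2 ratio was 0.039 with TMM factors, 0.035 with DESeq2 size factors, 0.086 as the mean of CPM per cell, 0.027 at resolution 0.5, 0.0079 with no mitochondrial limit (added) and -0.19 without the deep EE-like cluster (added).

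Among EE-like list medians, cell cycle was 0.084 with no minimum mean CPM and 0.10 with at most 10% mitochondrial UMIs (added). It was 0.43 with a pseudocount of 20 CPM, 0.47 with doublets kept, 0.43 at resolution 0.5 and 0.38 with no mitochondrial limit (added). Higher values were 1.69 as the mean of CPM per cell and, as added settings, 1.30 with each library clustered alone, 1.54 without the deep EE-like cluster and 1.37 with EE-like clusters weighted equally. Cytosolic ribosomal proteins were 0.29 with TMM factors, 0.29 with DESeq2 size factors, 0.31 with at least 500 genes, 0.28 with doublets kept, 0.077 at resolution 0.5 and, as added settings, 0.29 with at most 10% mitochondrial UMIs, -0.17 with each library clustered alone, 0.26 with no mitochondrial limit and 0.26 without the deep EE-like cluster. Nuclear-encoded respiratory chain was 0.11 with TMM factors, 0.10 with DESeq2 size factors, -0.21 as the mean of CPM per cell, -0.017 with at least 500 genes, -0.051 with doublets kept, -0.012 at resolution 0.5 and, as added settings, -0.15 with at most 10% mitochondrial UMIs, 0.18 with each library clustered alone, -0.051 with no mitochondrial limit, 0.096 without the deep EE-like cluster and 0.049 with EE-like clusters weighted equally. Digestive enzymes were -0.045 with no minimum mean CPM, 0.27 as the mean of CPM per cell, 1.57 with doublets kept and, as added settings, 0.24 with at most 10% mitochondrial UMIs, 0.072 with each library clustered alone, 1.09 with no mitochondrial limit, -0.19 without the deep EE-like cluster and 0.18 with EE-like clusters weighted equally, lipid metabolism 0.0058 as the mean of CPM per cell, and insulin and growth -0.019 with each library clustered alone (added). Heat shock proteins were 0.20 as the mean of CPM per cell, 0.25 with no minimum mean CPM and, as added settings, 0.23 with at most 10% mitochondrial UMIs, 0.18 with each library clustered alone, 0.097 without the deep EE-like cluster and 0.092 with EE-like clusters weighted equally.

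In progenitor-like cells apoptosis was 0.27 with TMM factors, 0.28 with DESeq2 size factors, -0.067 as the mean of CPM per cell, -0.0028 with no minimum mean CPM and -0.011 with each library clustered alone (added). Cytosolic ribosomal proteins were 0.45 with TMM factors, 0.46 with DESeq2 size factors and 0.26 as the mean of CPM per cell, nuclear-encoded respiratory chain 0.029, 0.041 and -0.33, and Notch 0.35, 0.36 and -0.19 in the same order. Heat shock proteins were 0.68 with TMM factors, 0.69 with DESeq2 size factors and 0.25 as the mean of CPM per cell. Digestive enzymes were 0.035 with no minimum mean CPM, 0.52 with at least 500 genes and 0.34 with no mitochondrial limit (added). In EC-like cells digestive enzymes were -0.16 with TMM factors, -0.14 with DESeq2 size factors, -0.29 as the mean of CPM per cell, -0.17 with no minimum mean CPM and -0.082 at resolution 0.5, and nuclear-encoded respiratory chain 0.073, 0.097 and -0.53 with the first 3 of these and -0.32 with no mitochondrial limit (added). In EE-like cells the log2 ratio of CG30466 was 0.97 with each library clustered alone and that of CCHa1 -0.93 with EE-like clusters weighted equally (both added). That of CG14312 was -0.95 and that of M7BP -0.98 with a pseudocount of 20 CPM, and that of CG14292 -0.92 with each library clustered alone (added). The progenitor-like log2 ratio of lncRNA:CR32368 was -0.39 and that of kirre 0.81 as the mean of CPM per cell, that of Chs2 0.76 with a pseudocount of 20 CPM and 0.81 with each library clustered alone (added), and the EC-like one of Ser6 0.44 as the mean of CPM per cell. The EC-like log2 ratio of CG33306 was 0.10 at resolution 0.5, and the log2 fold change of CG34386 between EE lineages and control in progenitor-like cells was 3.97 with no mitochondrial limit (added).

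Genes higher in EE lineages in EE-like cells numbered 230 with DESeq2 size factors in edgeR, 355 with no filter on low counts, 218 with at least 500 genes, 308 with doublets kept and 40 at resolution 2, and as added settings 320 with at most 10% mitochondrial UMIs, 219 with each library clustered alone, 384 with no mitochondrial limit and 64 without the EE-like clusters near absent from the unsorted libraries. Genes lower numbered 379 with no filter on low counts, 94 with the DESeq2 Wald test, 343 with doublets kept and 78 at resolution 2, and as added settings 315 with at most 10% mitochondrial UMIs, 444 with no mitochondrial limit and 67 without the EE-like clusters near absent from the unsorted libraries. In progenitor-like cells 0 were higher and 0 lower with no filter on low counts and at resolution 2, 7 and 4 with the DESeq2 Wald test, 23 higher with at least 500 genes and 59 higher with no mitochondrial limit (added). In EC-like cells 72 were higher and 41 lower with no filter on low counts, 22 and 5 with the DESeq2 Wald test, 48 and 9 with doublets kept, 41 and 5 at resolution 0.5, 119 and 29 with no mitochondrial limit (added), and 2 lower without the EC-like cluster held by control (added).

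Summed peptide hormones in control were 97369 CPM with TMM factors, 127619 as the mean of CPM per cell, 97064 with doublets kept and, as added settings, 136600 with each library clustered alone, 100557 without the EE-like clusters near absent from the unsorted libraries and 156061 without the deep EE-like cluster. In the library labelled Xrp1 overexpression they were 84528 CPM with TMM factors, 104554 as the mean of CPM per cell, 63842.6 with doublets kept and, as added settings, 90939 with each library clustered alone and 120556 without the deep EE-like cluster.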

Other observations

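Genes that differed at least 2-fold in the same direction in all 3 classes of the library labelled Xrp1 overexpression numbered 15 higher and 12 lower than in control, a set chosen after its values were seen. CG14645 stood at 825, 521 and 589.7 CPM in EE-like, progenitor-like and EC-like cells against 27.2, 14.9 and 35.3 in control, CG34324 at 231, 156 and 134 against 15.5, 12.02 and 10.4, and CG34220 at 174, 109 and 78.4 against 17.8, 10.1 and 7.76. Of the 15 higher genes, 8 lie on chromosome 2R, which holds 721 of the 3408 genes measured in the 3 classes, 21.2%, and of the 12 lower genes 1 does. CG14645, CG34324, CG34220 and CG3906 are top genes of unnamed cluster 23, which held 5 cells of control and 67 of the library labelled Xrp1 overexpression. CG12374 and epsilonTry, like CG34220 and CG3906 on 2R, are top genes of EC-like cluster 2. Free RNA from such cells was not tested for these genes, so the share on 2R cannot be read as an effect of position. All 15 higher genes but only 4 of the 12 lower genes lay outside the values of the other libraries. CG30466 lies at 15568960 to 15573170 on 2R and overlaps Flo1, on the opposite strand, at the 5′ ends of both.

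RpL22, a ribosomal protein gene on the X chromosome, stood at 823, 1804 and 988 CPM in control and at 351, 739 and 334 in the library labelled Xrp1 overexpression, in EE-like, progenitor-like and EC-like cells. EE lineages 1 and 2 were also below control, at 219 and 125 CPM in EE-like cells. The gene overlaps lncRNA:CR42491, which was lower in the same classes.

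Metallothionein RNA was concentrated in EE-like cluster 4 of the library labelled Xrp1 overexpression, with MtnD at 15676 CPM against 980 in control and MtnA at 8686 against 449. Near-identical copies in this family may share reads. By cluster, NPF in cluster 25 stood at 132096 CPM in control and 125927 in the library labelled Xrp1 overexpression, and Tk in cluster 11 at 15687 and 28283.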
